A study of Mus musculus with 4 samples.

How the data were processed

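ATAC-seq was measured in 4 libraries of sorted ChAT::GFP-positive cervical motor neurons from mouse embryos at day 12.5: 2 control and 2 Hoxa5-deficient, grouped by the genotype in their labels. Per the labels' protocols, cells were transposed with Tn5 and libraries were made with a Nextera kit. The submitters' processing notes name FastQC 0.11.9, Bowtie2 2.3.4.3, SAMtools 1.9, MACS2 2.2.4 and the build mm10, without parameters. Whether reads were shifted for the Tn5 insertion is not given in the sources used here. The authors deposited 1 peak list per library, called on each library separately, with no header and 10 columns.

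Each deposited row gives the interval, a score, a fold enrichment ratio over background at the summit, and −log10 of the p-value and of the q-value, in the form MACS2 writes. The deposited score is capped at 1000. The lowest −log10 p in each deposited list is just over 2, so the authors' lists end at about p = 0.01, a permissive threshold; from 90.3% to 92.8% of summits had a q-value under 0.05. Other deposited columns, start, end and summit offset, are base positions. A single interval can hold several summits, and from 323 to 363 peak numbers are missing per deposited list, so some peaks were removed before deposit by a filter not given in the sources used here. Fold and p-values belong to single peaks and were used only to rank or filter peaks within a list.

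Read depth is not stated, so it was recovered from the lists. Fold and p at a summit are functions of its tag pileup and local background, and for 100% of 20000 summits per library a whole-number pileup met the deposited −log10 p within 0.001. The lowest background was 5.43 and 4.39 tags in controls and 5.14 and 6.06 in mutants, which at the 150 bp tag extension seen in the steps is 362, 292, 343 and 404 tags per 10 kb. A deeper library gives more and weaker peaks at 1 threshold, so counts of regions carry this difference in depth.

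Intervals of the 4 lists on assembled chromosomes were merged where they overlapped by 1 bp or more, and a library had a region when any of its peaks fell in it. Control-only regions had a peak in both controls and neither mutant, mutant-only regions the reverse, and crossed regions a peak in exactly 1 library of each genotype. The group-to-crossed ratio is log2 of the product of control-only and mutant-only counts over the geometric mean of the products of opposite crossed counts, with a jackknife over 20 chromosomes. Jackknife intervals, also those of ratios of region counts, cover the sampling of regions and not differences between animals or libraries. Gene bodies came from a RefSeq table of the assembly GRCm38.p6, whose coordinates are those of mm10, with 21887 protein-coding genes used. It gives no strand, so a region was assigned to the protein-coding gene whose body holds its summit (the shortest if several), otherwise to the nearest body, in place of the nearest transcription start planned. Promoters were likewise replaced by both ends of each gene, 1 kb on each side. Coordinates are 1-based.

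A set of 19 gene lists (Hox genes and cofactors, motor neuron identity and columns, adhesion, guidance and synaptic genes, markers of other cell types and housekeeping genes) were fixed before the data were examined; 1 listed gene, Drgx, was not matched in the table. Some genes are in more than 1 list: 11 of 18 phrenic genes and 9 of 29 cadherins. Lists and genes with 5 or more regions were tested with two-sided Fisher's exact tests of group-specific against crossed regions, with Benjamini-Hochberg adjustment over 38 list tests, or over genes within a direction, and a threshold of 0.05. Odds ratios carry a continuity correction and 95% normal intervals on the log scale, which cover counting error only. Regions of 1 gene are not independent, so lists were also set against 10000 random gene lists matched on the number of regions per gene; this test, the strata of gene length, the strata of peak strength and the comparison of control-only with mutant-only regions were added after the data were seen. Named genes followed a rule fixed beforehand: Hox5 paralogs and Hox genes with a group-specific region; per direction, the genes of the 8 group-specific regions ranked highest by the lower of their percentiles; the 6 genes with most such regions; genes past the per-gene test; and up to 3 members per list and direction. Other genes named were chosen after their values were seen, and some genes that the rule names are not reported here.

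The tests were tried on simulated presence tables with the real gene assignment. With no genotype effect the log2 ratio averaged −0.00362 and 96% of 50 intervals held 0, and 0.0526% of 1900 list tests were called. Simulated regions were drawn independently, unlike real regions of 1 gene. These runs thus do not show the error rate of the list tests in the real data. In other runs 10% of regions were raised in mutants, and 1.5, 2 or 3 times that share at a random list of 25 genes. The list was then called in 0%, 20% and 90% of 20 runs each. The resulting enrichment of mutant-only over crossed regions was not recorded, and longer lists or lists with more regions were not simulated. Alternatives were equal peak numbers, −log10 q of 5 or more, autosomes only, overlap of 50% of a region, windows of 250 bp around summits, each library left out, a gene limit of 100 kb, a wider background and pairing by replicate number. Motif tests were planned and not run because no genome sequence was used here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.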

Results

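The series profiled open chromatin by ATAC-seq, in which the transposase Tn5 cuts and tags accessible DNA, in cervical spinal motor neurons of mouse embryos at embryonic day 12.5. Cells carrying the ChAT::GFP reporter, which marks cholinergic neurons, were sorted by their fluorescence from control embryos and from littermates deficient for Hoxa5, a homeodomain transcription factor of the Hox5 paralog group. There were 2 control and 2 Hoxa5-deficient libraries, called biological replicates by the submitters; the labels do not say how many embryos each one holds. The comparison asks which accessible regions of cervical motor neurons differ without Hoxa5. The control lists held 165866 and 163016 peak summits in 115089 and 113505 intervals, and the mutant lists held 192771 and 206114 summits in 127458 and 138248 intervals. Intervals covered 52.3 and 50.9 Mb in controls and 62.7 and 68.1 Mb in mutants. The genome-wide background recovered from the lists, which scales with read depth, was 362 and 292 tags per 10 kb in controls and 343 and 404 in mutants. Mutant library 1 thus had 0.946 of the depth of control library 1 and more intervals.

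The locus of Hoxa5 itself carried peaks in all 4 libraries. Within the gene, at chromosome 6, 52201754 to 52204587 (mm10), one interval of 276 to 337 bp lay at about 52202532 to 52202868 and another of 1150 to 1224 bp overlapped the gene's upper-coordinate end, from about 52203661 to 52204891. Both were called in each control and each mutant library. The labels do not state which part of Hoxa5 was removed, so these peaks do not check the genotype. Its paralogs Hoxb5 and Hoxc5 each had 1 region, present in all 4 libraries, and none of the 3 Hox5 genes had a region found in a single genotype.

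Regions called in both control libraries and neither mutant library (control-only) numbered 11 at the 39 Hox genes, against 7 called in both mutant libraries and neither control library (mutant-only), although mutant-only regions were 3.02 times as many in the whole genome. Of the 39 genes, 30 had neither kind. Control-only regions lay near Hoxa10 (chromosome 6, 52230482 to 52230930), Hoxa13, Hoxb9 with 2, Hoxc11, Hoxd3, Hoxb3 and Hoxc4 with 4. Mutant-only regions included 3 near Hoxc4 and 2 near Hoxb3. The odds ratio of control-only over mutant-only regions at Hox genes was 4.64 (95% interval 1.85 to 11.7; Fisher's exact test, exact adjusted p = 0.00319). Against random gene lists matched on region number the odds ratio was 3.41, with a permutation adjusted p of 0.0974. Peaks with −log10 q of 5 or more gave an odds ratio of 3.17 with an adjusted p of 0.123. Set against crossed regions, control-only regions were not clearly enriched at Hox genes, with 11 of 6825 against 13 of 8793. That odds ratio was 1.098 (95% interval 0.4996 to 2.41, Fisher's exact test, exact adjusted p = 0.912). The value of 4.64 thus came mainly from few mutant-only regions, at 7 of 20640 (odds ratio 0.236 against crossed regions).

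**Figure D1:**
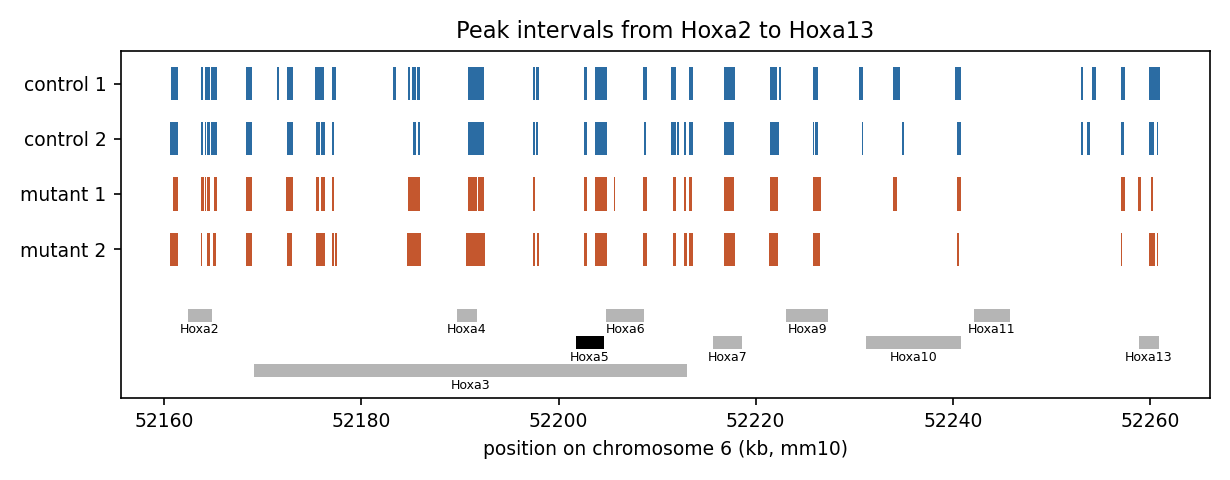
Peak intervals from Hoxa2 to Hoxa13 in the 2 control (blue) and 2 mutant (orange) libraries, with gene bodies below (Hoxa5 black); the horizontal axis is the position on chromosome 6 in kb. Both intervals over Hoxa5 are present in all 4 libraries, and the window holds 32 and 34 intervals in controls and 29 and 26 in mutants.

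Regions found in exactly 2 libraries lay mostly in libraries of the same genotype. Merging all intervals gave 199576 union regions, of which 65789 (33.0%) had a peak in all 4 libraries and 77549 in a single library. There were 6825 control-only and 20640 mutant-only regions, against 1765, 2909, 1685 and 2434 regions shared by exactly 1 control and 1 mutant library (crossed regions, mean 2198). Control-only regions were 3.10 times and mutant-only regions 9.39 times that mean. The log2 group-to-crossed ratio, which is 0 when libraries differ only in yield, was 4.94 (jackknife over 20 chromosomes, SE 0.042, 95% interval 4.86 to 5.02). This interval covers the sampling of regions within these 4 libraries and not the spread between animals. For the other splits of the 4 libraries into pairs the ratio was −2.61 and −2.33. The 3 values sum to 0 by construction, so these are not separate comparisons. Counting all shared regions, those in 3 or 4 libraries included, the mutants shared 99743, the controls 79280 and the crossed pairs from 76890 to 78867.

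Base-pair overlap was higher within genotypes as a share of the bases covered. The Jaccard index, the covered bases shared over those covered by either library, was 0.602 between controls and 0.650 between mutants. Across genotypes it was 0.507 ± 0.0150 (SD, 4 pairs), from 0.491 to 0.526, a difference of 0.119 from the within-genotype mean. The bases shared were 51.5 Mb between mutants, but 38.8 Mb between controls against 38.9 to 39.7 Mb across genotypes, so the controls' higher index reflects their smaller union. An exact permutation test over the 3 splits cannot go below p = 0.333, so this test could not pass 0.05 with 4 libraries.

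**Figure D2:**
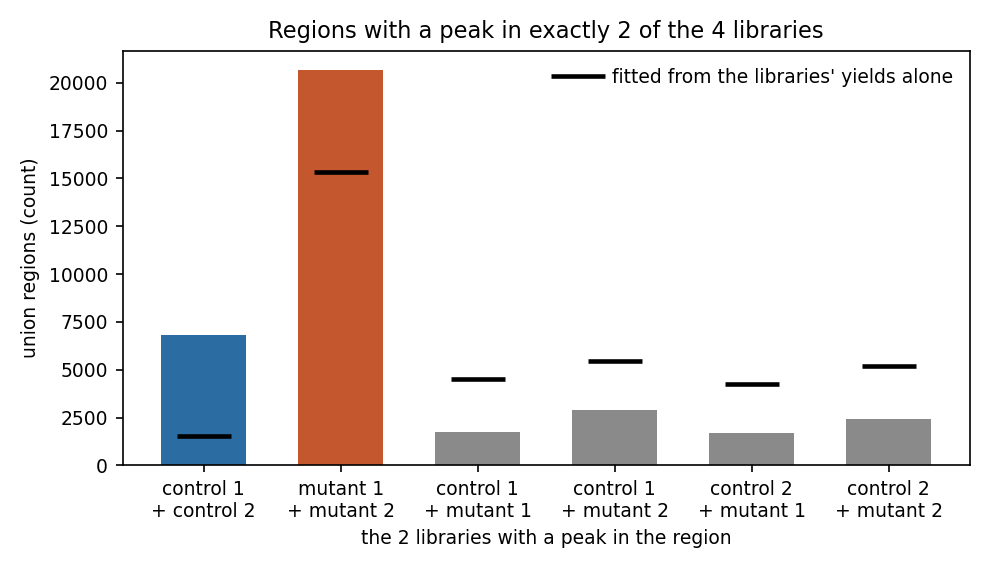
Number of union regions with a peak in exactly 2 of the 4 libraries, for each of the 6 pairs of libraries. Bars are observed counts (blue for the control pair, orange for the mutant pair, grey for crossed pairs). Black lines, called yields in the key, are counts fitted with 1 factor per library to these same 6 counts. The factors are not peak-list sizes, and the 20640 mutant-pair regions raise those of the mutants. The control pair shared 6825 regions where this fit gave 1519, and each crossed pair shared fewer than its fitted count. The fit thus does not show what differences in peak number alone would give.

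Group-specific regions lay mostly away from gene ends, and were weaker than regions shared by all 4 libraries and stronger than crossed regions. Near the ends of protein-coding genes, where promoters lie, the genotypes differed little: 17421 and 16952 of 43774 gene ends had a peak within 1 kb in controls and 17062 and 17509 in mutants. Of these ends 15668 had one in all 4 libraries, 234 in controls alone, 356 in mutants alone and 435 in crossed pairs. With equal numbers of peaks per library the order turned, to 321 control-only and 243 mutant-only ends. Mutant-only regions lay over 100 kb from any protein-coding gene in 26.4% of cases, against 14.9% of control-only and 15.6% of crossed regions. Their weaker peak ranked at a median percentile of 28.0 within its list, and that of control-only regions at 26.6, against 14.3 for crossed regions and 60.2 for the weakest peak of regions shared by all 4 libraries. Control-only regions fell to 4537 among peaks with −log10 q of 5 or more.

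The strongest control-only regions were ranked by the weaker of their percentiles within each control list. Of the first 8, 3 lay inside Foxp2 (chromosome 6, 15182818 to 15183323), Sox6 (chromosome 7, 115721507 to 115722377) and Satb1 (chromosome 17, 51775230 to 51775897), genes of transcription factors. Another (chromosome 16, 30065068 to 30065428) overlapped an end of Hes1, a Notch effector that keeps neural progenitors undifferentiated, with its summit 0.16 kb outside. The others lay in Nme8 and Lrrc75b, 268 kb from Ubash3b and 166 kb from Wdr11. The weaker percentile of the 8 regions ran from 76.6 to 81.5. Counted per gene, the most control-only regions were at Sox2, a progenitor transcription factor with 13, then Jarid2, Nfia, Msi2, Tcf4 and Zfp608 with 11 each. Mutant-only regions numbered 14, 7, 9, 13, 14 and 14 at the same genes. Sox2 spans only 2.467 kb and was assigned 78 regions in each library. Most of them thus lay outside Sox2, which was only the nearest protein-coding body.

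The genes with the most mutant-only regions were long. Rbfox1, a neuronal splicing regulator, had 46 mutant-only and 8 control-only regions. The synaptic adhesion genes Tenm3 and Adgrl2 had 45 and 41, against 9 each. Robo1, a receptor for Slit guidance cues, had 40 against 5, Auts2 had 40 against 8, and Cntnap2, a contactin-associated adhesion protein, had 35 against 1. The bodies of these 6 genes spanned from 174 kb for Adgrl2 to 2241 kb for Cntnap2. The strongest single mutant-only region lay inside Nrf1, a transcription factor gene (chromosome 6, 30112504 to 30113237), with percentiles of 91.6 and 94.7 in the mutant lists. The next ones lay in Camk4, Lrp1b, Gnat3 and Dgkh, 1.14 kb from Dtx2, 99.2 kb from Prl and 147 kb from Zwint.

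Tested gene by gene against crossed regions, few genes stood out. None of 752 genes passed in the control-only direction (Fisher's exact test with Benjamini-Hochberg adjustment), where 46 had an unadjusted p under 0.05 and the lowest adjusted p was 0.197. In the mutant-only direction 3 of 1840 genes passed, with 117 under an unadjusted p of 0.05. All 3 had fewer mutant-only than crossed regions: Zfp386 with 0 against 15 (exact adjusted p = 2.46e-05), Prl2c3 with 1 against 13 (0.001397) and Tcp10c with 1 against 10 (0.0277). All 15 crossed regions assigned to Zfp386 lay outside the gene, which was only the nearest protein-coding body. No gene passed with equal peak numbers or the stricter threshold. Leaving out control library 1 or 2 gave 1 and 9 genes, and leaving out mutant library 1 or 2 gave 14 and 21.

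Gene lists fixed before the data were examined passed in 7 of 38 tests against crossed regions, and none of the 7 passed against random gene lists matched on region number, with permutation adjusted p from 0.214 to 0.956. Neural progenitor genes were enriched near control-only regions, with 47 of 6825 regions against 29 of 8793 crossed regions (odds ratio 2.08, 95% interval 1.31 to 3.30; exact adjusted p = 0.0124). Genes of glutamate and acetylcholine receptors and synaptic organisers were under-represented near control-only regions (0.656, 0.494 to 0.871; exact adjusted p = 0.0161). Near mutant-only regions the phrenic motor column list (odds ratio 1.67, 1.25 to 2.22), the cadherins (1.57, 1.24 to 1.997), other cell adhesion genes (1.44, 1.17 to 1.77) and the synaptic list (1.403, 1.16 to 1.69) were each enriched at an exact adjusted p = 0.00415. Hox genes were under-represented there (0.236, 0.0968 to 0.577; exact adjusted p = 0.0130).

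Against matched random lists the progenitor, control-only synaptic and Hox odds ratios kept most of their size, at 2.03, 0.650 and 0.307, while the phrenic, cadherin, adhesion and mutant-only synaptic ones shrank to 1.21, 1.14, 1.03 and 1.04. Within strata of gene length none of the 7 passed either. There the progenitor, control-only synaptic, Hox, phrenic and cadherin odds ratios were 2.12, 0.670, 0.280, 1.48 and 1.401, each at an adjusted p of 0.0696, and only the adhesion and mutant-only synaptic ones went to about 1, at 1.04 and 0.987. Within strata of peak strength 5 of the 7 passed, and the progenitor list (1.995, adjusted p 0.0649) and the control-only synaptic list (0.702, 0.109) did not. Among peaks with −log10 q of 5 or more the progenitor list had 2.01 (exact adjusted p = 0.0922). The Hox call ended with that threshold (odds ratio 0.297, exact adjusted p = 0.185) and with summit windows (0.376, 0.274), and the adhesion call with equal peak numbers (1.23, 0.191). Within 100 kb of a gene the phrenic (1.30, 0.410), cadherin (1.24, 0.583) and mutant-only synaptic (1.35, 0.0741) calls ended. The control-only synaptic call ended with the stricter threshold (0.712, 0.304), within 100 kb (0.667, 0.1099), with the wider background (0.786, 0.0926) and without control library 1 (0.915, 0.373).

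Setting control-only directly against mutant-only regions, a comparison chosen after the data were seen, separated 9 of 19 lists. The neural progenitor list held 47 control-only and 45 mutant-only regions, an odds ratio of 3.17 (95% interval 2.11 to 4.77; exact adjusted p = 6.93e-07), and 3.19 within strata of gene length. Matched random gene lists gave a permutation adjusted p of 0.0019. Of its 24 genes, 10 had more control-only and 7 more mutant-only regions. Dll1, a Notch ligand, had 4 against 0, Irx3 had 4 against 5 and Gli3 had 3 against 8. Taken alone, Sox2 was the 1 gene of this list with an adjusted p under 0.05 adjusted over the list alone (0.0471). It held 13 of the 47 control-only and 14 of the 45 mutant-only regions, most of them outside the gene.

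Glial genes differed in the same direction, with 29 control-only and 37 mutant-only regions (odds ratio 2.38, 1.47 to 3.87; exact adjusted p = 0.00265, and 0.0114 against matched random lists). Nfia, which drives gliogenesis, had 11 against 9, Slc1a3 4 against 2, and Nfib 4 against 12. Spinal interneuron genes had 34 against 54 (odds ratio 1.92, 1.25 to 2.94, exact adjusted p = 0.01001). Against matched random lists their odds ratio was 1.78, with a permutation adjusted p of 0.0974. Lmx1b with 5 against 1 and Pax2 with 5 against 2 passed when adjusted over the list alone, and Barhl2 with 1 against 10 leaned to mutants. Both lists are markers of cells other than motor neurons. The share of a library's regions at progenitor genes was 0.416% and 0.398% in controls and 0.332% and 0.334% in mutants, and that at glial genes was 0.264% and 0.260% against 0.231% and 0.211%. The numbers of regions hardly differed, at 456 and 425 against 408 and 447 for progenitor genes and 290 and 278 against 283 and 283 for glial genes, so the shares fell mainly because the mutant lists held more regions elsewhere.

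Adhesion, synaptic and motor neuron genes leaned in the mutant direction. They passed in tests that count regions but not against matched random gene lists, where their odds ratios ran from 0.674 to 0.843. The phrenic motor column list, genes linked to the diaphragm-innervating motor neurons that need Hox5 genes, had 41 control-only and 231 mutant-only regions (odds ratio 0.539, 0.387 to 0.751; exact adjusted p = 0.000374, and 0.386 against matched random lists). Of its 18 genes, 16 had more mutant-only regions, as the larger mutant-only total alone would favour. Cdh11 had 27 mutant-only against 0 control-only regions, Cdh8 22 against 3, Erbb4 21 against 5 and Cdh2 16 against 6. Cdh11 was the 1 gene of the list past the threshold when adjusted over the list alone (0.00891). Cadherins, which share 8 genes with the phrenic list, had 317 against 58 (0.553, 0.418 to 0.732; exact adjusted p = 6.03e-05, and 0.368 against matched random lists), led by Cdh11, Cdh13 with 25 against 6 and Pcdh7 with 23 against 1. Other cell adhesion genes, of the immunoglobulin superfamily apart from the contactin-associated Cntnap2, Cntnap4 and Cntnap5a, had 394 against 78 (0.597, 0.468 to 0.762; exact adjusted p = 6.03e-05, and 0.496 against matched random lists), led by Cntnap2, Lsamp with 35 against 4 and Ntm with 28 against 7. The synaptic list had 469 against 73 (0.468, 0.365 to 0.599; exact adjusted p = 1.27e-09, and 0.112 against matched random lists), with Tenm2 at 35 against 5. Motor neuron identity genes had 119 against 23 (0.593, 0.381 to 0.924; exact adjusted p = 0.0315, and 0.395 against matched random lists), led by Ebf1 with 30 against 0, the 1 gene adjusted over the list alone (0.00348), and by Slit2 with 15 against 2; Slit3, with 17 against 10, lay below the 3.02 of the whole genome.

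Within strata of gene length the calls of the other adhesion and motor neuron identity lists ended too, at odds ratios of 0.879 and 0.648. Counting only regions within 100 kb of a gene ended the cadherin call (odds ratio 0.856, exact adjusted p = 0.619) and the phrenic call (0.767, 0.324). The phrenic call also ended with the stricter threshold (0.792, 0.319) and without mutant library 1 (0.799, 0.137), and the motor neuron identity call with the stricter threshold (0.632, 0.172), with overlap of 50% of a region (0.714, 0.129), with summit windows (0.707, 0.199), and without mutant library 1 (0.706, 0.0856) or 2 (0.783, 0.241). Over all genes, the same comparison gene by gene called 0 of 1716 genes (Fisher's exact test; 147 with an unadjusted p under 0.05, lowest adjusted p 0.278).

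**Figure D3:**
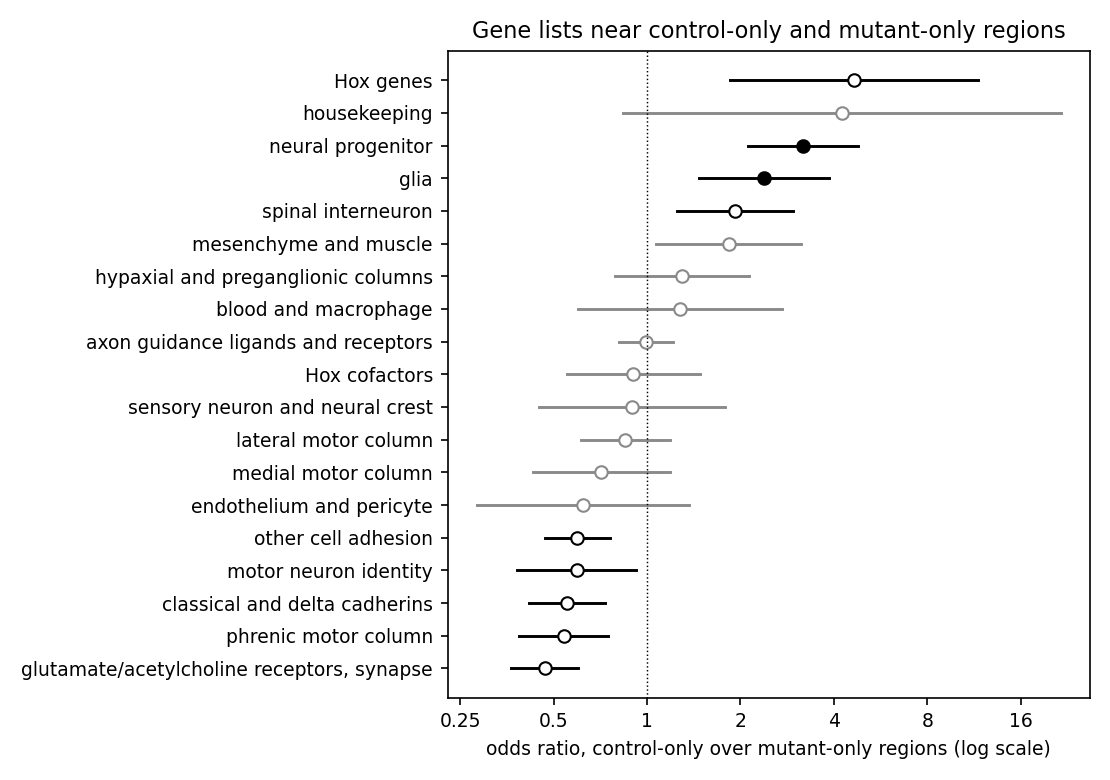
Odds ratio of control-only over mutant-only regions for each of 19 gene lists, on a log axis; lines are 95% intervals, black for lists with an adjusted p under 0.05 in Fisher's exact test and grey for the others, and filled points passed against matched random gene lists too. Neural progenitor (3.17) and glia (2.38) are the 2 lists with filled points.

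The remaining 10 lists did not separate control-only from mutant-only regions. Axon guidance genes were alike in both, at 1.89% of control-only and 1.904% of mutant-only regions (odds ratio 0.995, 0.814 to 1.22), with Efna5 at 5 against 28 and Plxna2 at 10 against 11. Among other motor columns, the medial list had an odds ratio of 0.712 (0.429 to 1.18), the lateral list 0.851 (0.612 to 1.18) and the hypaxial and preganglionic list 1.30 (0.791 to 2.13). Hox cofactors had 0.905 (0.552 to 1.48), with Pbx3 at 7 against 12 and Meis1 at 4 against 14. Markers of other tissues that a sort can carry went both ways: mesenchyme and muscle 1.83 (1.07 to 3.14, exact adjusted p = 0.0807), blood and macrophages 1.28 (0.598 to 2.73), sensory neurons and neural crest 0.894 (0.449 to 1.78), and endothelium and pericytes 0.621 (0.283 to 1.36). Housekeeping genes had 3 control-only and 2 mutant-only regions (4.24, 0.835 to 21.5). Per library, both controls lay above both mutants in the share of regions for 6 lists and below for 11, where chance gives 33.3% of lists apart, or 6.33 of 19. The lists share genes and the same 4 library totals, so they are not separate trials. These numbers therefore do not measure an excess over chance.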

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

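Nearest gene ends, strata, matched random lists, the comparison of control-only with mutant-only regions and the Jaccard index with a library left out were chosen after seeing the data. The group-to-crossed log2 ratio stayed above 0 under all 5 alternatives run, from 4.89 with summit windows to 6.83 with the stricter threshold; it needs 4 libraries, so none could be left out. Control-only regions ranged from 4537 with the stricter threshold to 8624 with equal peak numbers, and mutant-only regions from 14368 to 26756. The Jaccard difference rose to 0.151 with the stricter threshold, and ran from 0.0835 to 0.149 with a library left out. With a window of 250 bp, 221 gene ends had a peak in mutants alone. The number of genes past the threshold fell from 3 to 0 with equal peak numbers and with the stricter threshold, and to 1 within 100 kb of a gene, where 3 lists passed. A background of all other regions in 2 or more libraries gave 13 lists and 83 genes. Within gene-length strata 0 lists passed, with an odds ratio of 0.987 for mutant-only regions near synaptic genes, and against matched random lists 0 passed; the cause of these changes was not tested, but both alternatives compare genes of like length or region number. With a library left out, a group-specific region needs fewer libraries, so counts of regions, gene ends and lists rose: control-only regions ran from 10076 to 26905, mutant-only regions from 26909 to 47068, control-only gene ends from 348 to 941, mutant-only gene ends from 531 to 957, and lists from 12 to 19. Genes past the threshold, 3 in the main analysis, fell to 1 without control library 1 and rose to between 9 and 21 otherwise. The replicate block, over pairs of libraries with the same number, gave 13 lists and 77 genes, and it counts regions of single libraries. The labels do not say whether equal numbers mark a litter. Deviations of libraries with the same number correlated at −0.004, which does not settle whether they were paired. Over all settings, the odds ratios of the 7 called lists were past the threshold in 78 cases, in the same direction but not past it in 26 and reversed in 1. Those of control-only over mutant-only regions were past it in 107 cases and in the same direction in the other 19; the progenitor and glial lists passed in all 14 settings each, from 2.05 to 3.82 and from 1.70 to 3.28. Counts of regions at named genes stayed within 1.5 times in 264 cases and moved further in 72. Motif tests and all their alternatives were not run, for want of a genome sequence. Depth limits the weaker peaks: control library 2 had 0.808 of the depth of control library 1, so a region absent there may lie below the threshold.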

Other observations

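Equal peak numbers, the stricter threshold and the list tests against crossed regions were chosen before the data were seen, and the other tests here after the results were seen. Control-only regions at Hox genes included 5 at paralog groups 6 to 13 (Hoxb9 with 2, Hoxa10, Hoxa13 and Hoxc11), genes used at more caudal levels of the body, and 6 at groups 1 to 5. The 7 mutant-only regions all lay at groups 1 to 5, and the difference did not pass (Fisher's exact test, p = 0.101). No chromosome held a different share of group-specific than of crossed regions at the threshold, chromosome 6 with Hoxa5 included (exact adjusted p = 0.831 for control-only and 0.922 for mutant-only regions).

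The 3 genes with fewer mutant-only than crossed regions were each assigned many regions called in control library 1. Of the 15 crossed regions assigned to Zfp386, 13 involved control library 1, and 20 further regions were called in control library 1 alone. For Prl2c3 these were 11 of 13 and 21, and for Tcp10c 8 of 10 and 16. The 15 regions of Zfp386 spanned 859.8 kb of chromosome 12, from 115151962 to 116011770. All lay outside the gene, which starts at 116047714, and were assigned to it as the nearest protein-coding gene.

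Of the regions found in exactly 2 libraries, pairs of 1 genotype held more than pairs of different genotypes. An overall yield per library cancels from the log2 ratio by construction. With equal peak numbers the ratio was 5.16 (jackknife over chromosomes, 95% interval 5.07 to 5.25). Because of that cancelling, this value is no separate test of unequal peak numbers. Among peaks with −log10 q of 5 or more the ratio was 6.83 (6.69 to 6.96), so the weakest called peaks were not needed for the pattern. That cut sets a new threshold with peaks just under it, so it cannot exclude presence calls lost near a threshold. The labels name no batch, and 1 of 3 splits of 4 libraries (0.333) is the genotype split, so preparation or sequencing that followed genotype cannot be told apart from the loss of Hoxa5. Both remain open, as do differences between the sorted cell populations.

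Mutant-only regions outnumbered control-only regions. In these libraries a larger number of called peaks in mutants did not account for all of it. With equal peak numbers there were still 1.78 mutant-only regions per control-only region, down from 3.02. The jackknife 95% interval was 1.68 to 1.88, over regions and not animals. The ratio was 1.19 (0.991 to 1.43) within 1 kb of gene ends and 3.12 (2.96 to 3.29) elsewhere. Most regions near gene ends were in all 4 libraries, so the places were also compared within strata of the peak strength of group-specific regions. There the first ratio was 0.383 times the second (0.318 to 0.460), against 0.382 without strata. The strata hold only regions already called in 1 genotype, so they do not count the regions in each place that could still gain a peak. A gain in yield alike at all regions is therefore neither shown nor excluded. The excess lay away from gene ends, and a change in distal accessibility without Hoxa5 may account for it, as may a preparation that favours distal regions, neither of which was tested.

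A larger share of control-only than of mutant-only regions lay near progenitor and glial genes. The numbers were alike, at 47 and 45 for progenitor and 29 and 37 for glial genes, so a gain of mutant-only regions at other genes may account for the odds. Against crossed regions the control-only odds were 2.08 (1.31 to 3.30) for progenitor genes, which did not pass against matched random lists, and 1.69 (0.977 to 2.93, adjusted p 0.243) for glial genes, which leaves this open. Gene length did not account for it, as the odds ratio within length strata was 3.19 for progenitor and 2.44 for glial genes. A lower share of motor neurons in the control sort could raise markers of all other cells alike. The progenitor odds, however, were 2.67 times (gene bootstrap, 95% interval 1.498 to 5.38) those of sensory, endothelial, blood and mesenchymal markers pooled. They were 2.38 times (1.37 to 4.81) those of that pool without cadherin genes. With glia and interneurons added to the full pool they were 1.96 times (1.19 to 3.69) as high. A loss of purity that raised all other cell types alike thus does not account for the progenitor list. A loss that added some cell types more than others was not tested and remains open. The glial odds were 2.01 times (0.944 to 4.44) those of the first pool, which leaves an even loss open for glia. Carry-over of neighbouring spinal cells is neither shown nor excluded: interneuron odds were 1.60 times (0.745 to 3.45) those of the non-spinal types, but against crossed regions interneuron genes were not clearly enriched in control-only regions (1.16, 0.729 to 1.83) and were fewer in mutant-only ones (0.602, 0.398 to 0.910, adjusted p 0.104). More progenitor-like or younger ChAT::GFP-positive cells in the control sort, a preparation that followed genotype and an effect of Hoxa5 loss on progenitor gene regions all remain possible, and no expression data were used here to part them.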
